A study of Mus musculus with 12 samples.

How the data were processed

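The series holds RNA-seq of mouse spermatogenic cells. Per the labels, priSG-A, plpSC, pacSC and rST were isolated by sedimentation (STAPUT, which separates cells by size), SSCs were cultured, RNA was extracted with Trizol, and groups of 2 libraries each were labelled as replicates. The labels do not say that replicates come from separate animals or cultures, so p-values measure the spread between these samples. The age of each stage is confounded with the stage, apart from plpSC and pacSC, which share an age.

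For the 8 germ cell libraries the deposited values are FPKM with a lower and an upper confidence bound per gene, per the file headers. The submitters' processing notes name TopHat2 2.0.6, Cuffdiff and BWA with build mm9, without saying which step each served. No strand is stated, so antisense transcripts are not separable from sense ones. Each file held 23021 entries. The 469 entries that share a symbol (259 symbols) were summed, which left 22552 symbols, of which 25 had been turned into calendar dates in the files (22 of them expressed). Locus coordinates (mm9) came from the file for pacSC replicate 2, which gives them for all genes, and 14095 of the 14111 expressed symbols (99.89%) lay on 1 chromosome. The files hold no read totals. With the bounds read as 2 SD of a counting error, each library's depth was recovered as effective fragments: 27164132 and 30514026 for priSG-A, 34923958 and 25391163 for plpSC, 25035858 and 28705005 for pacSC, and 28337884 and 23520448 for rST. Between 57.4% and 65.0% of the recovered values lay within 0.05 of a whole number, so these depths are estimates. The small RNAs Rpph1, Rmrp and Rprl3 took 18.4% and 22.2% of the FPKM sum in the priSG-A libraries, 7.64% and 19.1% in plpSC, 6.43% and 3.9% in pacSC, and 2.14% and 1.82% in rST, but at most 1.72% of the recovered fragments of a library.

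For the 4 SSC libraries the deposited lists give 1 count of back-splice junction reads per circRNA, with its type, per the file headers. Host genes were assigned by overlap and not read from the lists. A host is a gene whose mm9 locus, among those described above, contains the whole circRNA. Host results used the 26205 circRNAs inside 1 such locus and left out 124 inside several. The column layout is that of CIRI, whose version, minimum of reads and annotation are not stated. A circRNA that a list lacks was entered as 0. The lists hold no non-junction reads, so the circular share at each junction could not be computed and is not reported.

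Gene tests were run with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) with 4 stage means, all 8 libraries, 4 residual degrees of freedom, and eBayes with trend. Genes with an FPKM of at least 1 in at least 2 libraries were tested for each adjacent step, two-sided, and called at a Benjamini-Hochberg adjusted p under 0.05. The 23 gene lists were undifferentiated spermatogonia, differentiating spermatogonia, meiotic recombination and synapsis, pachytene spermatocyte, round spermatid, spermatogenic transcription regulators, piRNA pathway, mitotic cell cycle, DNA methylation and imprinted, testis histone variants and chromatin remodelling, X-linked housekeeping genes and parents of retrogenes, autosomal retrogenes of X-linked parents, X-linked germ cell genes, long non-coding RNA, circular RNA biogenesis factors, glycolysis and sperm energy metabolism, ribosomal proteins, Sertoli cell, Leydig cell, peritubular myoid and stromal cell, macrophage, endothelial cell and erythroid cell. Some genes are on more than 1 list. Each list, and the X and Y chromosomes, was tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists or over both chromosomes of a step. The chromosome tests were first left unadjusted in the alternatives and were adjusted after the results were seen, which moved the estimated-correlation result at the step to pacSC from called to not called.

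Junction reads were tested with edgeR 4.0.16 (quasi-likelihood, TMM factors) for circRNAs in at least 2 of the 4 libraries, and with DESeq2 1.42.0 as an alternative. Shares have exact binomial intervals at 95%. Junction reads were thinned to the shallowest library in 100 draws, and a circRNA counted with at least 2 reads. Host gene levels were compared by 100000 resamples. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the rest.

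The named genes were, per step, the 6 largest rises and 6 largest falls among called genes whose libraries did not overlap between the stages and with a mean of at least 20 FPKM in the higher stage, up to 4 called members per list by size of change, and 12 fixed genes. Named circRNAs were the 5 with the most treated junction reads among those in all 4 libraries and the 3 rises and 3 falls of smallest p, and named hosts were the 5 with the most circRNAs in at least 2 libraries, with ties by alphabet. The groups, comparisons, gene lists, naming rule and most alternatives were set before the data were examined. Those alternatives were a pseudocount of 0.1, no filter, a minimum of 5 FPKM, quantile normalization, median centring, a replicate block, eBayes without trend, only the 4 libraries compared, each library left out, a 2-fold minimum, and for circRNAs DESeq2, no TMM, other minimums of libraries or reads, thinning and ends within 10 bases. Added after seeing the data were edgeR on the effective fragments, a weight per stage, and resampling of hosts within 20 bins of locus length. No rescaling without the most abundant small RNAs was run. Where 1 library was left out, the lone library of a stage was assumed to vary like the other stages.

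The tests were run on simulated data with 200 changed genes among 14111, in 1 run with 2- and 4-fold changes (100 genes each) and another with 8-fold changes. Apart from its change, each gene was simulated with the same mean and spread at all stages. The real stages differed in spread, with fitted stage weights from 0.19 in plpSC to 3.41 in priSG-A. The rates below therefore do not measure what unequal spread does to false calls at the 3 steps. For plpSC against priSG-A limma recovered 18% of 2-fold and 78% of 4-fold changes with 6 false calls, and 93.5% of 8-fold changes with 11 false calls. For pacSC against plpSC it recovered 21% and 80% with 6 false calls and 93% with 8, and for rST against pacSC 18% and 79% with 4 false calls and 93% with 10. With 200 changed among 9976 circRNAs edgeR recovered 8% of 8-fold and 35% of 32-fold changes with 1 false call. Most changes of that size were thus missed in the simulation, where depth, spread and number of libraries were not varied apart. Every circRNA there had the same spread and, apart from its change, the same share in all 4 libraries. No minimum of reads for listing was simulated. The rates therefore do not measure what unequal spread, shifts in make-up or unlisted circRNAs do in the real lists.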

Results

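Total RNA of mouse male germ cells (F1 of DBA/2 and C57BL6) was sequenced at 4 stages of spermatogenesis, with 2 libraries per stage. The stages were primitive type A spermatogonia (priSG-A) at 7 days postpartum, preleptotene spermatocytes (plpSC, cells about to enter meiosis) at 17 days, pachytene spermatocytes (pacSC, cells in meiotic prophase with paired chromosomes) at 17 days, and round spermatids (rST, haploid cells after meiosis) at 60 days. A further 4 libraries came from cultured spermatogonial stem cells (SSCs, 5 days postpartum). Of these, 2 had been treated with RNase R, an exonuclease that digests linear RNA, and 2 had not, and each gave a list of circular RNAs (circRNAs). The germ cell files held 22552 gene symbols, of which 14111 were expressed, meaning an FPKM of at least 1 in at least 2 of the 8 libraries. The depth recovered from the confidence bounds of the FPKM values lay between 23520448 fragments (rST replicate 2) and 34923958 (plpSC replicate 1). Across genes, which are not independent replicates, Pearson's r between replicates was 0.986 for priSG-A, 0.935 for plpSC, 0.958 for pacSC and 0.994 for rST. The plpSC replicates were no closer to each other than plpSC replicate 1 was to pacSC replicate 1 (r = 0.937). Levels below are mean FPKM ± SD (n = 2) per stage, fold changes are differences of log2(FPKM + 1), and positions are on mm9.

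Most of the transcriptome changed over the 4 stages. The limma F test called 12491 of the 14111 genes, 8841 of them with at least a 2-fold change at an adjacent step. Of the called genes 7149 (57.2%) had their highest mean in priSG-A, 3179 (25.5%) in rST, 1724 (13.8%) in pacSC and 439 (3.5%) in plpSC. The priSG-A libraries also held transcripts of Sertoli cell genes (Clu at 774.5 and 830.8, Amh at 81.67 and 61.07). Some peaks in priSG-A may therefore be those of another cell type. Zbtb16, a transcription factor of undifferentiated spermatogonia (9:48462402-48644050), was at 15.2 ± 1.88 in priSG-A, 2.01 ± 0.783 in plpSC, 0.506 ± 0.300 in pacSC and 0.545 ± 0.106 in rST. Sycp3, a component of the synaptonemal complex (10:87922332-87935981), was at 83.7 ± 10.6, 207 ± 43.9, 244 ± 99.6 and 78.8 ± 9.38 in the same order. Prm1, a protamine that packs sperm DNA (16:10796425-10796916), was at 37.9 ± 41.9, 66.4 ± 8.38, 1203 ± 1610 and 17640 ± 2300. Its pacSC mean joined libraries at 66.1 (replicate 1) and 2340 (replicate 2). Xist stayed at or below 0.222 in all 8 libraries and was outside the expressed set. The median log2 change of all expressed genes was -0.35 from priSG-A to plpSC, -0.25 from plpSC to pacSC and -0.03 from pacSC to rST. After quantile normalization these medians were -0.35, 0.03 and -0.13, and after centring each library on its median they were -0.17, 0.15 and 0.03.

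**Figure D1:**
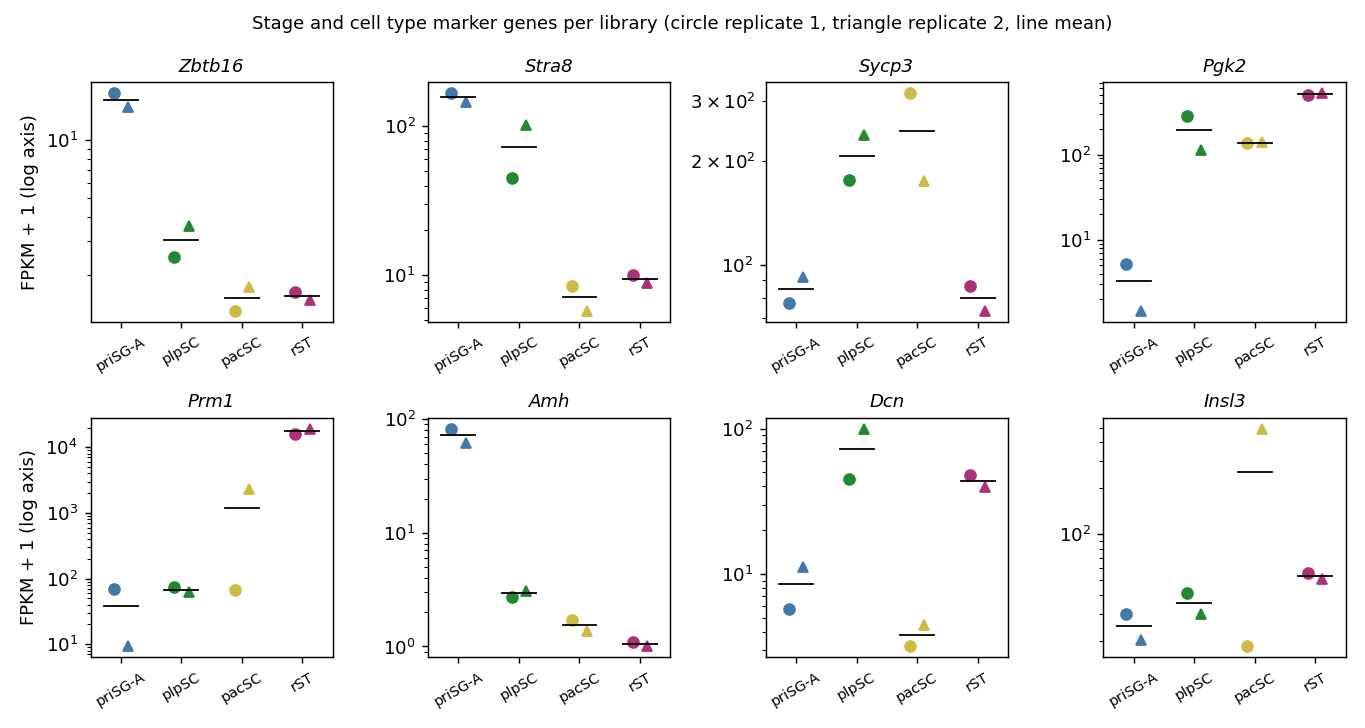
FPKM + 1 on a log axis at the 4 stages for 8 marker genes, with circles for replicate 1, triangles for replicate 2 and a line through the stage means. Zbtb16 and Amh are highest in priSG-A and Prm1 in rST, while Prm1 and Insl3 lie far apart in the pacSC replicates (Prm1 at 66.1 and 2340, Insl3 at 17.3 and 492).

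Between priSG-A and plpSC, the step towards meiotic entry, the list of undifferentiated spermatogonia was called down and those of meiotic recombination and synapsis, of pachytene spermatocytes and of round spermatids were called up. All 4 calls ended with an estimated correlation (adjusted p = 0.505 for each). RNA of later cells in the plpSC libraries was not excluded, so the rises may not be those of cells entering meiosis. Pearson's r of plpSC replicate 1 was 0.937 and 0.939 with the pacSC libraries and 0.916 with rST replicate 1. With the priSG-A libraries it was 0.545 and 0.486. For plpSC replicate 2 it was 0.886 and 0.861 with pacSC, 0.784 with rST replicate 1, and 0.727 and 0.683 with priSG-A. Of the 21 expressed genes of undifferentiated spermatogonia, 19 fell (19 adjusted over the list alone) and 2 were not called, with a median change of -1.90 (camera adjusted p = 2.96e-06, and adjusted p = 0.505 with an estimated correlation). Itga6, an integrin subunit, went from 55.4 ± 1.13 to 3.63 ± 1.17, Lin28a, an RNA-binding protein that blocks let-7 processing, from 31.1 ± 2.2 to 2.59 ± 0.577, and Gfra1, the receptor for GDNF (19:58311182-58528956), from 6.47 ± 0.252 to 1.43 ± 0.146. Among 15 genes of differentiating spermatogonia 10 fell and 2 rose (10 and 3 adjusted over the list alone), and the list was not called by camera (median -1.17, adjusted p = 0.151, and adjusted p = 0.578 with an estimated correlation). Stra8, needed for the switch to meiosis (6:34870960-34889342), fell from 156 ± 14.6 to 72.1 ± 40, and Kit, a receptor tyrosine kinase (5:75971012-76052746), from 14.02 ± 0.717 to 5.83 ± 3.55, while Dmrtb1 rose from 18.2 ± 2.54 to 135 ± 71.6.

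Meiotic recombination and synapsis genes rose in 18 of 35 cases and fell in 1 (17 and 1 adjusted over the list alone). The median was 1.02 (camera adjusted p = 4.36e-05, and adjusted p = 0.505 with an estimated correlation). Spo11, which makes the meiotic DNA breaks (2:172805343-172819077), rose from 0.809 ± 0.133 to 11.1 ± 2.29, and Syce1 from 44.3 ± 1.45 to 338 ± 174. Of 30 pachytene spermatocyte genes 22 rose and 1 fell (23 and 1 adjusted over the list alone). The median was 3.00 (camera adjusted p = 4.64e-10, and adjusted p = 0.505 with an estimated correlation). Tcte3 rose from 9.43 ± 5.77 to 918 ± 490.0 and Ldhc, the germ cell lactate dehydrogenase, from 43.6 ± 58.6 to 1373 ± 806. Of 41 round spermatid genes 33 rose and 8 were not called (33 adjusted over the list alone). The median was 3.81 (camera adjusted p = 3.93e-11, and adjusted p = 0.505 with an estimated correlation). Acrv1, an acrosomal protein (9:36500805-36506422), rose from 0.8 ± 0.945 to 90.2 ± 69.3 and Actl7b from 2.96 ± 3.34 to 358 ± 258, whereas Prm1 (limma adjusted p = 0.44) and Tnp1 (limma adjusted p = 0.1) were not called. The plpSC replicates differed in these genes, with Ldhc at 1943 and 803 and Acrv1 at 139 and 41.2 in replicates 1 and 2. In priSG-A, Ldhc was at 85.0 in replicate 1 and 2.13 in replicate 2. Prm1 (67.5 and 8.25), Tnp2 (23.96 and 2.17), Acrv1 (1.47 and 0.132) and Pgk2 (4.15 and 0.454) were likewise higher in priSG-A replicate 1. Sycp3 (76.2 and 91.2) was not. The source of these transcripts in priSG-A was not tested.

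Further germ cell groups rose in part. The piRNA pathway, which silences transposons, had 13 rises and 5 falls among 25 genes (13 and 5 adjusted over the list alone; median 0.66, camera adjusted p = 0.011, and adjusted p = 0.556 with an estimated correlation), with Piwil1 (5:129242121-129261349) going from 1.71 ± 0.551 to 27.4 ± 3.25 and Tdrd6 from 1.35 ± 1.61 to 141 ± 79.2. Spermatogenic transcription regulators had 18 rises and 12 falls among 35 (18 and 12 adjusted over the list alone). The median was 1.04 (camera adjusted p = 0.0257, and adjusted p = 0.505 with an estimated correlation). Crem, an activator of postmeiotic genes, rose from 4.22 ± 0.736 to 86.5 ± 51.2. Glycolysis and sperm energy metabolism had 21 rises and 14 falls among 36 (21 and 14 adjusted over the list alone). The median was 1.76 (camera adjusted p = 0.0152, and adjusted p = 0.538 with an estimated correlation). Pgam2 rose from 4.52 ± 5.13 to 392 ± 245. Autosomal retrogenes of X-linked parents rose in 11 of 14 cases (11 adjusted over the list alone). The median was 1.92 (camera adjusted p = 6.23e-05, and adjusted p = 0.505 with an estimated correlation). Pgk2 (17:40343963-40345554) went from 2.3 ± 2.61 to 195 ± 119, and its X-linked parent Pgk1 (X:103382463-103399038) fell from 26.1 ± 2.4 to 10.1 ± 4.61. Testis histone variants and chromatin remodelling had 12 rises and 9 falls among 31 (12 and 9 adjusted over the list alone), with a median of -0.08 that centring turned to 0.10, a mean of 0.53, and no call (camera upward, adjusted p = 0.151, and adjusted p = 0.505 with an estimated correlation). Hist1h1t, the testis linker histone H1t (13:23787680-23788591), rose from 21.4 ± 0.0196 to 145 ± 0.622.

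Genes of cell division and of DNA methylation fell in part. The mitotic cell cycle list had 17 falls and 3 rises among 35 (15 and 3 adjusted over the list alone; median -0.69) and no call by camera (adjusted p = 0.12, and adjusted p = 0.578 with an estimated correlation), with Ccna2 falling from 51.9 ± 0.343 to 12.7 ± 4.55. DNA methylation and imprinted genes fell in 14 of 20 cases (14 adjusted over the list alone). The median was -1.07 (camera adjusted p = 0.00993, and adjusted p = 0.578 with an estimated correlation). Dnmt3b, a de novo DNA methyltransferase, went from 30.7 ± 1.2 to 4.4 ± 1.39 and the imprinted H19 from 26.9 ± 2.47 to 3.37 ± 1.94. Markers of somatic testis cells moved in both directions. Sertoli cell genes fell in 20 of 22 cases (20 adjusted over the list alone). The median was -2.47 (camera adjusted p = 1.41e-06, and adjusted p = 0.505 with an estimated correlation). Amh, the anti-Müllerian hormone (10:80267993-80270393), fell from 71.4 ± 14.6 to 1.93 ± 0.252, and Wt1 (2:104966686-105013771) from 28.8 ± 2.01 to 3.27 ± 1.75. Peritubular myoid and stromal genes rose in 14 of 22 cases and fell in 1 (14 and 1 adjusted over the list alone). The median was 1.56 (camera adjusted p = 0.000468, and adjusted p = 0.556 with an estimated correlation). Dcn went from 7.47 ± 3.81 to 71.5 ± 38.7. Erythroid genes rose in 5 of 6 cases (5 adjusted over the list alone). The median was 3.31 (camera adjusted p = 0.0012, and adjusted p = 0.505 with an estimated correlation). Hba-a1 went from 9.16 ± 1.21 to 283 ± 134, but the globin copies are near identical, so which copy changed is uncertain. Leydig cell genes had 4 falls and 1 rise among 12 (4 and 1 adjusted over the list alone). The median was -1.48 (camera adjusted p = 0.354, and adjusted p = 0.749 with an estimated correlation). Endothelial genes had 6 falls among 15 (6 adjusted over the list alone). The median was -0.25 (camera adjusted p = 0.3, and adjusted p = 0.684 with an estimated correlation).

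The test called 9272 genes at this step, 3449 higher and 5823 lower in plpSC, and 6545 of them changed at least 2-fold. Since 20 of 22 Sertoli cell genes were among the falls, part of the falls may reflect RNA of another cell type in priSG-A. The largest rises with full separation of the libraries were 1700001F09Rik (log2 change 7.22 ± 0.81 SE, limma adjusted p = 0.00034), Cmtm2b, Cmtm2a, Gm3925, Pdcl2 and Hrasls5, where Cmtm2a and Cmtm2b are close copies and not told apart with certainty. The largest falls were AI848285 (-4.95 ± 0.22 SE, limma adjusted p = 6.2e-05), Amh, Sel1l3, Kazald1, Bcan and Pdlim4. Quantile normalization gave 3369 higher and 5970 lower and centring 3837 and 4942. EdgeR on the fragments recovered from the bounds, which changes the test as well as the scale, gave 4132 higher and 3163 lower. The direction of the majority was thus not settled. The main fit pooled the spread of all 4 stages, and plpSC had the lowest stage weight (0.19). With a weight per stage 7302 genes were called, and with only the 4 libraries compared 7857. Macrophage genes had 2 rises among 14 (1 adjusted over the list alone; median 0.30, camera adjusted p = 0.0641, and adjusted p = 0.578 with an estimated correlation), and without plpSC replicate 1 this list was called (median 0.59, camera adjusted p = 0.00182). The transcription regulators lost their call without plpSC replicate 2, with a median of 0.941 against 1.038 with all libraries. Of the 105 genes named for this step, 9 lost their call without priSG-A replicate 1, 5 without priSG-A replicate 2, 7 without plpSC replicate 1, 3 without plpSC replicate 2 and 1 without each rST library.

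Between plpSC and pacSC, both taken at 17 days, falls outnumbered rises on the scale of the files. The lists of differentiating spermatogonia and of the mitotic cell cycle were called down, and those of the piRNA pathway and of pachytene spermatocytes were called up. All 4 calls ended with an estimated correlation (adjusted p = 0.52, 0.52, 0.52 and 0.549). Hist1h1t rose from 145 ± 0.622 to 719 ± 20.6 and Piwil1 from 27.4 ± 3.25 to 106 ± 3.41, and both fell again in rST. Aym1 had the largest rise with full separation (6.75 ± 2.16 to 57.4 ± 1.21, log2 change 2.94 ± 0.3 SE, limma adjusted p = 0.0065), ahead of Gm5878, 4930525D18Rik, D130017N08Rik, Pou5f2 and 1700006A11Rik. Genes of differentiating spermatogonia fell in 9 of 15 cases (10 adjusted over the list alone). The median was -1.31 (camera adjusted p = 0.00327, and adjusted p = 0.52 with an estimated correlation). Stra8 went from 72.1 ± 40 to 6.13 ± 1.95 and Dmrt1 from 26.4 ± 9.17 to 3.6 ± 0.0725. Of 35 meiotic recombination and synapsis genes 11 fell and 4 rose (11 and 4 adjusted over the list alone). The list had a median of -0.30 (-0.18 after quantile normalization and 0.10 after centring) and a mean of -0.45, while camera pointed upward without a call (adjusted p = 0.765, and adjusted p = 0.944 with an estimated correlation). Dmc1, the meiotic recombinase, fell from 20.1 ± 14.4 to 2.57 ± 1.47 and Prdm9, which sets the sites of recombination, from 9.46 ± 6.66 to 0.752 ± 0.159, while Sycp3 stood at 207 ± 43.9 and 244 ± 99.6 (limma adjusted p = 0.7).

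The mitotic cell cycle list fell in 19 of 35 cases (19 adjusted over the list alone). The median was -0.90 (camera adjusted p = 0.00226, and adjusted p = 0.52 with an estimated correlation). Mcm2, a subunit of the replicative helicase, went from 21.8 ± 8.22 to 2.89 ± 0.0587. DNA methylation and imprinted genes fell in 8 of 20 cases (9 adjusted over the list alone). The median was -0.78 (camera adjusted p = 0.0156, and adjusted p = 0.661 with an estimated correlation). Dnmt3a went from 4.24 ± 2.13 to 0.662 ± 0.137. The piRNA pathway had 5 rises and 1 fall among 25 (5 and 1 adjusted over the list alone). The median was 0.43 (camera adjusted p = 1.75e-05, and adjusted p = 0.52 with an estimated correlation). Tdrd5 rose from 18.6 ± 1.55 to 66.7 ± 16.7 and Tdrd1 from 29.2 ± 1.21 to 78.8 ± 12.7. Pachytene spermatocyte genes had 5 rises and 2 falls among 30 (4 and 2 adjusted over the list alone). The median was 0.40 (camera adjusted p = 0.000259, and adjusted p = 0.549 with an estimated correlation). Autosomal retrogenes had 3 rises among 14 (5 adjusted over the list alone). The median was 0.43 (camera adjusted p = 0.00167, and adjusted p = 0.52 with an estimated correlation). Pdha2 went from 70.8 ± 32.1 to 149 ± 28. For the 41 round spermatid genes camera called an upward shift (adjusted p = 0.0291, and adjusted p = 0.855 with an estimated correlation), although Tekt5 was the single called member. None passed adjusted over the list alone or with edgeR on recovered fragments, and 1 was higher and 1 lower at an unadjusted limma p under 0.05. The median was -0.09 (0.31 after centring) and the mean 0.18. This list moved with pacSC replicate 2, where Prm1 was at 2340 against 66.1 in replicate 1, and without that library its median was -1.20 (camera adjusted p = 0.241).

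Undifferentiated spermatogonial genes had 9 falls and 1 rise among 21 (11 and 1 adjusted over the list alone). The median was -0.53 (camera adjusted p = 0.0532, and adjusted p = 0.661 with an estimated correlation). The rise was Id4, from 7.92 ± 0.00952 to 28.6 ± 2.52. Transcription regulators had 15 falls and 2 rises among 35 (15 and 4 adjusted over the list alone). The median was -0.56 (camera adjusted p = 0.258, and adjusted p = 0.595 with an estimated correlation). Testis histone variants had 8 falls and 2 rises among 31 (8 and 2 adjusted over the list alone), a median of -0.21 (0.19 after centring), a mean of -0.33 and no call (camera upward, adjusted p = 0.78, and adjusted p = 0.855 with an estimated correlation). Glycolysis genes had 9 falls and 3 rises among 36 (9 and 3 adjusted over the list alone), a median of -0.19 (0.22 after centring), a mean of -0.22 and no call (camera upward, adjusted p = 0.549, and adjusted p = 0.855 with an estimated correlation). Gapdh fell from 61.0 ± 29.7 to 18.9 ± 5.88.

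Somatic and blood cell markers were lower in pacSC than in plpSC apart from the Leydig genes. Peritubular myoid and stromal genes fell in 19 of 22 cases (20 adjusted over the list alone). The median was -2.34 (camera adjusted p = 3.39e-06, and adjusted p = 0.52 with an estimated correlation). Col1a2 went from 49.1 ± 34.9 to 0.843 ± 0.224. Macrophage genes fell in 11 of 14 cases (13 adjusted over the list alone). The median was -1.13 (camera adjusted p = 0.000234, and adjusted p = 0.52 with an estimated correlation). Lyz2 went from 19.7 ± 5.93 to 3.42 ± 0.448. Sertoli cell genes fell in 14 of 22 cases (21 adjusted over the list alone). The median was -0.99 (camera adjusted p = 3.04e-05, and adjusted p = 0.52 with an estimated correlation). Endothelial genes fell in 7 of 15 cases (9 adjusted over the list alone). The median was -0.65 (camera adjusted p = 0.0173, and adjusted p = 0.587 with an estimated correlation). Cd34 went from 12.8 ± 6.81 to 1.3 ± 0.428. Erythroid genes fell in 5 of 6 cases (5 adjusted over the list alone; median -3.76, camera adjusted p = 0.00211, and adjusted p = 0.52 with an estimated correlation), and the largest falls of the step were the globins Hba-a1 (log2 change -7.54 ± 0.55 SE, limma adjusted p = 0.0065) and Beta-s, ahead of Col1a2, Snora43, Dcn and Col3a1. None of the 12 Leydig genes was called by limma, adjusted over the list alone, or by edgeR on recovered fragments, and 1 was lower at an unadjusted p under 0.05. Their median was 0.59 (camera adjusted p = 0.105, and adjusted p = 0.782 with an estimated correlation). Insl3 stood at 17.3 in pacSC replicate 1 and 492 in replicate 2. Without pacSC replicate 1 the Leydig list was called upward (median 2.14, camera adjusted p = 1.29e-08) and without replicate 2 downward (median -0.97, camera adjusted p = 0.0308).

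At this step 3646 genes were called, 596 higher and 3050 lower in pacSC, 2235 of them with at least a 2-fold change. Quantile normalization gave 1243 higher and 1083 lower, centring 1357 and 1239, and edgeR on recovered fragments 914 and 2056. The main fit pooled the spread of all 4 stages. The stage weights, lower where replicates differ more, were 0.190 in plpSC, 0.664 in pacSC, 2.325 in rST and 3.41 in priSG-A. The 3646 calls thus rest partly on the smaller spread of stages outside this step, and the p-values may be too small. The count moved with the libraries used, and the part of unequal spread in this was not tested. It was 1074 without pacSC replicate 1, 1265 without pacSC replicate 2, 7263 without plpSC replicate 1, 2065 and 2075 without priSG-A replicates 1 and 2, and 1685 and 1680 without rST replicates 1 and 2. With only the 4 libraries compared it was 680, and with a weight per stage (plpSC 0.190, priSG-A 3.41) 1 gene passed, Hba-a2 (log2 change -4.11, limma adjusted p = 0.0018), with 3378 at an unadjusted p under 0.05. Without plpSC replicate 2 the calls of the pachytene (camera adjusted p = 0.0741), round spermatid (0.652), DNA methylation (0.155), retrogene (0.0546) and endothelial (0.0893) lists ended. The medians of the pachytene and retrogene lists were then below 0 (-0.09 and -0.23, against 0.40 and 0.43 with all libraries), those of the round spermatid, DNA methylation and endothelial lists -0.70, -0.40 and -0.46 (against -0.09, -0.78 and -0.65). Without pacSC replicate 1 the call of DNA methylation ended (median -0.72, camera adjusted p = 0.0518). The undifferentiated list was called without priSG-A replicate 1 (camera adjusted p = 0.0411), priSG-A replicate 2 (0.0433) or plpSC replicate 1 (0.0455). Of the 90 genes named for this step, 27 lost their call without pacSC replicate 1, 33 without pacSC replicate 2, 14 without plpSC replicate 2, 2 without plpSC replicate 1, 12 and 11 without priSG-A replicates 1 and 2, and 19 without each rST library.

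Between pacSC and rST, which compares meiotic with haploid cells, the round spermatid list was called up and the lists of meiotic recombination and synapsis and of the piRNA pathway were called down. All 3 calls ended with an estimated correlation (adjusted p = 0.733 for each). Of 41 round spermatid genes 37 rose and 4 were not called (39 adjusted over the list alone). The median was 2.93 (camera adjusted p = 1.41e-11, and adjusted p = 0.733 with an estimated correlation). Prm1 rose from 1203 ± 1610 to 17640 ± 2300, Prm2 from 336 ± 446 to 5637 ± 677, and the transition proteins Tnp1 (1:73061649-73062473) from 533 ± 692 to 5745 ± 142 and Tnp2 from 425 ± 546 to 5606 ± 584. The protamine and transition protein genes made up 0.04% of the FPKM sum in pacSC replicate 1, 1.35% in pacSC replicate 2, 6.59% in rST replicate 1 and 7.4% in rST replicate 2. The linker histone H1fnt rose from 48.4 ± 52.9 to 481 ± 13.9 and the X-linked histone variant H2afb1 from 25.5 ± 26.9 to 442 ± 22.5, while Hist1h1t fell from 719 ± 20.6 to 66.1 ± 33.4. The histone list as a whole had 12 falls and 8 rises among 31 (13 and 9 adjusted over the list alone), a median of 0.17 (-0.02 after quantile normalization), a mean of 0.02 and no call (camera downward, adjusted p = 0.796, and adjusted p = 0.931 with an estimated correlation).

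Meiotic recombination and synapsis genes fell in 16 of 35 cases and rose in 3 (17 and 3 adjusted over the list alone). The median was -0.69 (camera adjusted p = 0.00448, and adjusted p = 0.733 with an estimated correlation). Sycp3 fell from 244 ± 99.6 to 78.8 ± 9.38 and Hormad1 from 107 ± 32.5 to 23.2 ± 2.45, whereas Rec8, a meiotic cohesin, rose from 9.05 ± 4.71 to 40.4 ± 1.81. The piRNA pathway fell in 15 of 25 cases and rose in 1 (16 and 2 adjusted over the list alone). The median was -1.04 (camera adjusted p = 0.000281, and adjusted p = 0.733 with an estimated correlation). Piwil1 fell from 106 ± 3.41 to 17.3 ± 3.32 and Tdrd5 from 66.7 ± 16.7 to 7.52 ± 2.99, and the riser was Kif17 (10.4 ± 9.39 to 68.0 ± 7.77). Pachytene spermatocyte genes split into 6 falls and 5 rises among 30 (6 and 5 adjusted over the list alone), with a median of -0.03 (0.03 after centring) and no call (camera adjusted p = 0.786, and adjusted p = 0.931 with an estimated correlation). Pou5f2 fell from 53.8 ± 5.51 to 4.3 ± 2.5 and Calr3, an endoplasmic reticulum chaperone, rose from 7.21 ± 7.59 to 52.0 ± 3.28. Transcription regulators had 11 rises and 2 falls among 35 (11 and 2 adjusted over the list alone). The median was 0.30 (camera adjusted p = 0.0405, and adjusted p = 0.733 with an estimated correlation). Rfx1 rose from 1.66 ± 0.912 to 14 ± 2.02 and Klf4 from 5.97 ± 2.83 to 38.0 ± 5.46.

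Glycolysis and sperm energy metabolism had 10 rises and 5 falls among 36 (10 and 6 adjusted over the list alone), a median of 0.14 (-0.19 after quantile normalization) and no call (camera adjusted p = 0.659, and adjusted p = 0.931 with an estimated correlation). The spermatid enzymes Gapdhs (14.6 ± 15.1 to 141 ± 15.3) and Aldoart2 (19.5 ± 15.6 to 147 ± 2.8) were among the rises. Retrogenes had 3 rises and 3 falls among 14 (3 and 3 adjusted over the list alone), a median of -0.02 (0.04 after centring), a mean of 0.24 and no call (camera downward, adjusted p = 0.786, and adjusted p = 0.931 with an estimated correlation). Pgk2 rose from 137 ± 2.87 to 510 ± 19.9 and Ubl4b from 18.2 ± 21.2 to 179 ± 10.2. The undifferentiated list had 1 fall among 21, Id4 (1 adjusted over the list alone; median 0.02, -0.05 after quantile normalization, mean -0.11, camera downward, adjusted p = 0.826, and adjusted p = 0.931 with an estimated correlation). The differentiating list had 1 rise among 15, Elmo1 (1 adjusted over the list alone). The median was 0.24 (camera adjusted p = 0.244, and adjusted p = 0.784 with an estimated correlation). Mitotic genes had 6 falls and 4 rises among 35 (5 and 4 adjusted over the list alone; median -0.04, 0.02 after centring, camera adjusted p = 0.709, and adjusted p = 0.931 with an estimated correlation). DNA methylation and imprinted genes had 2 of each among 20 (2 and 2 adjusted over the list alone; median -0.03, 0.03 after centring, camera adjusted p = 0.786, and adjusted p = 0.931 with an estimated correlation).

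Some somatic markers were higher in rST than in pacSC. Macrophage genes rose in 10 of 14 cases (11 adjusted over the list alone). The median was 1.16 (camera adjusted p = 3.23e-06, and adjusted p = 0.733 with an estimated correlation). Lyz2 went from 3.42 ± 0.448 to 24.5 ± 3.68 and the complement gene C1qb from 1.04 ± 0.35 to 9.83 ± 2.15. Endothelial genes rose in 9 of 15 cases (9 adjusted over the list alone). The median was 0.73 (camera adjusted p = 0.000807, and adjusted p = 0.733 with an estimated correlation). Peritubular myoid and stromal genes rose in 5 of 22 cases (5 adjusted over the list alone). The median was 0.98 (camera adjusted p = 0.000667, and adjusted p = 0.733 with an estimated correlation). Dcn went from 2.81 ± 0.906 to 42.7 ± 6.16. Sertoli cell genes fell in 7 of 22 cases (7 adjusted over the list alone). The median was -0.54 (camera adjusted p = 0.00607, and adjusted p = 0.733 with an estimated correlation). Clu went from 79.6 ± 22.7 to 17.7 ± 4.11. Erythroid genes had 2 rises among 6 (2 adjusted over the list alone). The median was 0.40 (camera adjusted p = 0.167, and adjusted p = 0.733 with an estimated correlation). Of the 12 Leydig genes Fdx1 alone was called by limma, downward, and none passed adjusted over the list alone (1 at an unadjusted p under 0.05) or with edgeR on recovered fragments (median -0.83, camera adjusted p = 0.192, and adjusted p = 0.922 with an estimated correlation), and without pacSC replicate 1 the list was called downward (median -2.75, camera adjusted p = 1.45e-07).

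The test called 4856 genes at this step, 2495 higher and 2361 lower in rST, 3258 of them with at least a 2-fold change. Centring gave 2631 higher and 2045 lower, while quantile normalization gave 2359 and 2799 and edgeR on recovered fragments 1815 and 2123. The direction of the majority was thus not settled. With a weight per stage 6528 genes were called, and with only the 4 libraries compared 6308. The largest rises were 1700027A15Rik (163 ± 213 to 3447 ± 77.8, log2 change 5.75 ± 1.31 SE, limma adjusted p = 0.014), Prm2, Prm1, 1700015G11Rik, Oxct2b and Tnp2. The largest falls were the small RNAs Scarna3a and Snora28, both at 0 in the rST libraries, then Hist1h1t (log2 change -3.52 ± 0.34 SE, limma adjusted p = 0.0034), Pou5f2, Aym1 and 1700006A11Rik. The count was 2 without rST replicate 2 (Snhg9 and Snora81, named after their values were seen), 1577 without rST replicate 1, 1818 without pacSC replicate 1, and 7363 and 7364 without plpSC replicates 1 and 2. The transcription regulators lost their call without plpSC replicate 1 (median 0.297), plpSC replicate 2 (0.297), pacSC replicate 2 (0.253) or rST replicate 2 (0.248). Their median with all libraries was 0.297. Of the 92 genes named for this step, 86 lost their call without rST replicate 2, 38 without rST replicate 1, 34 without pacSC replicate 1, 6 without pacSC replicate 2 and 4 without each priSG-A library.

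**Figure D2:**
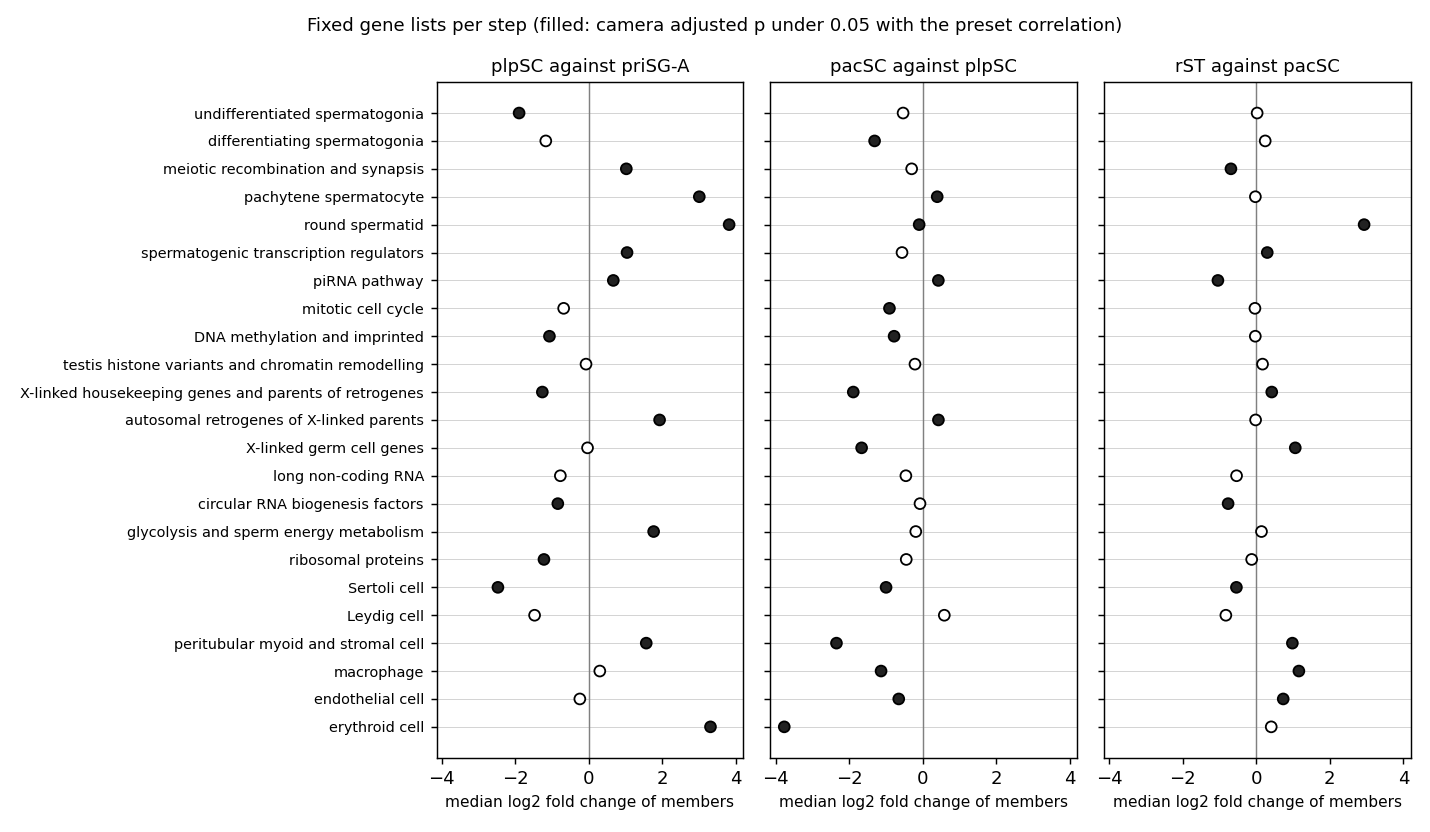
Median log2 fold change of the expressed members of 23 gene lists (vertical axis) at the 3 steps, with filled points for lists called by camera with the preset correlation. Undifferentiated spermatogonia lie at -1.90 at the step to plpSC and round spermatid genes at 2.93 at the step to rST.

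X-linked and Y-linked genes fell in pacSC and rose in rST relative to autosomal ones, which bears on the silencing of the sex chromosomes in pachytene spermatocytes. The calls of both chromosomes at these steps ended with an estimated correlation (adjusted p = 0.0903 and 0.17 for each). On the Y chromosome 8 of 10 expressed genes were lower in pacSC (median difference from the autosomal one -1.20, camera adjusted p = 2e-04) and 6 higher in rST (0.96, camera adjusted p = 0.0019). From priSG-A to plpSC 4 fell and 3 rose (difference -0.02, camera upward, adjusted p = 0.975, and adjusted p = 0.986 with an estimated correlation). From plpSC to pacSC 429 of the 648 expressed X-linked genes (66.2%) fell and none rose in the limma test, against 19.4% lower and 4.4% higher of the 13437 autosomal genes. No X-linked gene was higher at an unadjusted p under 0.05 or with edgeR on recovered fragments, which called 359 lower. The X-linked median change lay 0.92 below the autosomal one (-1.14 against -0.22; camera adjusted p = 4.78e-24, and adjusted p = 0.0903 with an estimated correlation). In rST 226 X-linked genes rose and 9 fell (median difference 0.38, camera adjusted p = 2.35e-09, and adjusted p = 0.17 with an estimated correlation). With a pseudocount of 0.1 the difference was -1.49 at the step to pacSC and 0.76 at the step to rST. Per library, the X-linked median log2 level minus the autosomal one was -0.54 and -0.50 in priSG-A, -0.64 and -0.63 in plpSC, -1.59 and -1.58 in pacSC, and -1.02 and -1.04 in rST. From priSG-A to plpSC 162 X-linked genes rose and 342 fell, and the difference was not called (median difference -0.38, camera adjusted p = 0.249, and adjusted p = 0.986 with an estimated correlation). Medians of the stromal, macrophage and endothelial lists also fell in pacSC (-2.34, -1.13 and -0.65) and rose in rST (0.98, 1.16 and 0.73). Sertoli cell genes fell at both steps (-0.99 and -0.54), and the Leydig list was called at neither. RNA of cells without silenced sex chromosomes would raise the X-linked level. Its part in these changes was not tested.

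Both X-linked lists were called down in pacSC and up in rST, and differences between the lists were not tested. All 4 calls ended with an estimated correlation (adjusted p = 0.52 and 0.733 for the housekeeping list, 0.158 and 0.205 for the germ cell list). X-linked housekeeping genes and parents of retrogenes fell in 20 of 27 cases from priSG-A to plpSC (22 adjusted over the list alone; median -1.27, camera adjusted p = 0.0012, and adjusted p = 0.556 with an estimated correlation) and in 26 of 27 from plpSC to pacSC (26 adjusted over the list alone). The median was -1.89 (camera adjusted p = 6.04e-11, and adjusted p = 0.52 with an estimated correlation). Rpl39 went from 150 ± 8.15 in priSG-A to 52.2 ± 30, 5.74 ± 0.695 and 5.18 ± 0.755 in plpSC, pacSC and rST, and Hprt, a purine salvage enzyme, fell from 16.8 ± 9.46 in plpSC to 2.28 ± 0.372 in pacSC. In rST 11 of the 27 rose (13 adjusted over the list alone). The median was 0.42 (camera adjusted p = 0.00118, and adjusted p = 0.733 with an estimated correlation). Eif1ax went from 9.73 ± 4.76 to 49.1 ± 1.39. X-linked germ cell genes had 12 rises and 8 falls among 30 in plpSC (12 and 8 adjusted over the list alone), a median of -0.04 (0.14 after quantile normalization and 0.15 after centring) with a mean of 0.80 and no call (camera upward, adjusted p = 0.151, and adjusted p = 0.505 with an estimated correlation). They fell in 20 of 30 cases in pacSC (21 adjusted over the list alone; median -1.66, camera adjusted p = 2.89e-06, and adjusted p = 0.158 with an estimated correlation) and rose in 14 of 30 in rST (15 adjusted over the list alone). The median was 1.06 (camera adjusted p = 1.27e-05, and adjusted p = 0.205 with an estimated correlation). Tex11, a meiotic crossover factor, fell from 32.7 ± 18.2 in plpSC to 2.74 ± 0.85 in pacSC, and Akap4, a scaffold of the sperm tail, rose from 83.5 ± 86.9 in pacSC to 797 ± 54.2 in rST.

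**Figure D3:**
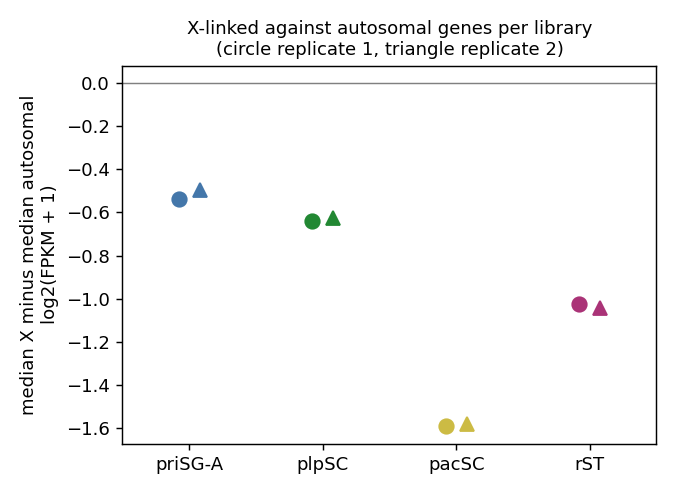
Median log2(FPKM + 1) of expressed X-linked genes minus that of autosomal genes, 1 point per library, by stage. Both pacSC libraries (-1.59 and -1.58) lie below all others, and the rST libraries (-1.02 and -1.04) lie between them and plpSC.

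In the cultured SSCs, 29643 different circRNAs were listed over the 4 libraries, and more were listed after RNase R. The treated libraries listed 12266 and 25415 circRNAs from 263855 and 560991 back-splice junction reads, and the untreated libraries 2601 and 3578 from 21754 and 30400 reads. The means were 18840.5 ± 9297.7 (SD, n = 2) and 3089.5 ± 690.8 (SD, n = 2), and an exact permutation test of 2 against 2 cannot give p below 0.33. At 21754 junction reads each, and with at least 2 reads per circRNA, the treated libraries held 3058 and 2848 circRNAs and the untreated 2590 and 2973. The minimum of 2 leaves out 11 circRNAs that untreated replicate 1 lists with 1 read. Of the circRNAs, 19667 were in 1 library, 6930 in 2, 1851 in 3 and 1195 in all 4. Of the 1368 listed in both untreated libraries, 1195 (87.4%) were also in both treated ones. Exon-derived circRNAs made up 68.8% of those in 1 library and 88.0% of those in all 4. Intergenic circRNAs had a share of 7.7% (exact 95% interval 7.2 to 8.2) and 8.3% (7.9 to 8.6) in the treated libraries, and 14.6% (13.2 to 16.0) and 12.9% (11.8 to 14) in the untreated ones. Intronic circRNAs had a share of 15.0% (14.4 to 15.7) and 16.1% (15.7 to 16.6) in the treated libraries, and 9.5% (8.4 to 10.7) and 9.6% (8.6 to 10.6) in the untreated ones. These intervals cover counting error only. Of the 2917 intergenic circRNAs, 1621 overlapped no gene locus of the files, 785 overlapped part of 1 gene and 511 overlapped several.

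**Figure D4:**
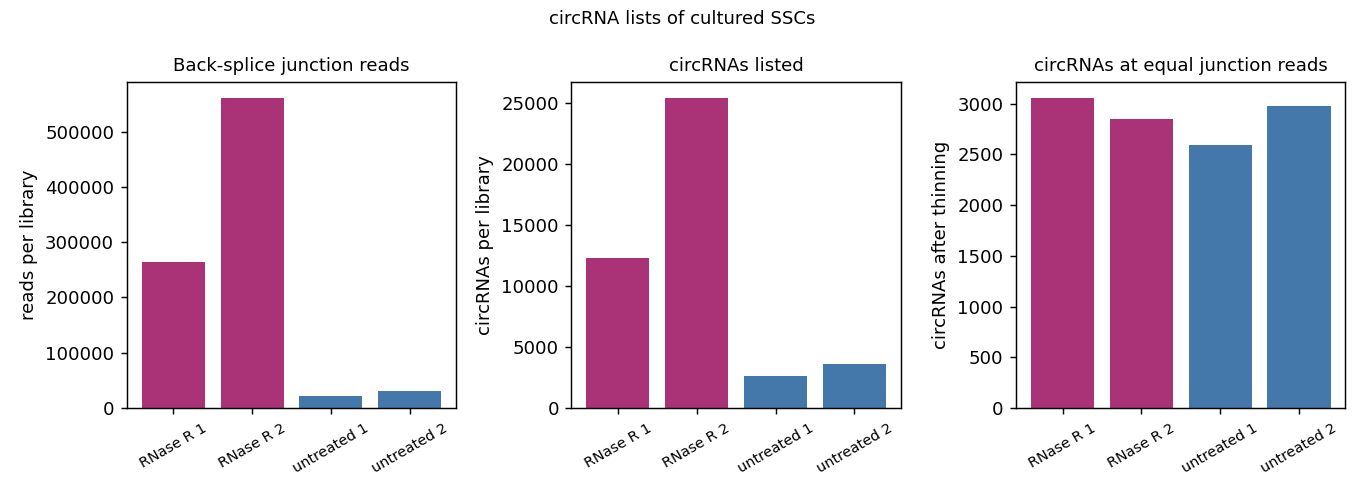
Bars for each SSC library (RNase R replicates 1 and 2, untreated replicates 1 and 2) with the number of junction reads, of circRNAs listed, and of circRNAs at equal junction reads. Listed numbers run from 2601 to 25415, and at 21754 reads each, with at least 2 reads per circRNA, from 2590 to 3058.

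Junction reads of each circRNA relative to the others of its library were compared between treated and untreated SSCs, and circRNAs were called in both directions. The circRNAs with the most reads were led by 1 over Elf2 that the lists give as intergenic (3:51111972-51129957, 3031 and 5346 reads treated, 199 and 197 untreated, log2 change 1.35, edgeR adjusted p = 0.0083). It ends 48 bases past the gene and so has no host by overlap. Next came another intergenic one between Rbmxl2 and Syt9 (7:114428296-114429244, 2177, 3983, 109 and 176 reads in the same order, log2 change 1.43, edgeR adjusted p = 0.01). An exonic one of Cnot6l, a deadenylase subunit, followed (5:96557962-96563151, 1926, 3977, 111 and 181 reads, log2 change 1.31, edgeR adjusted p = 0.022). Those of Epb4.1l5 (1:121464373-121475654; 1329, 3878, 125 and 206 reads, edgeR adjusted p = 0.16) and Pphln1 (15:93254445-93295676; 1409, 3551, 91 and 179 reads, edgeR adjusted p = 0.075) were not called. The rises of smallest p were an intergenic circRNA between D10Wsu102e and Aldh1l2 (10:82870537-82872179; 210 and 683 reads treated, edgeR adjusted p = 0.00053), Spopl (2:23392848-23401099; 168 and 552 reads, edgeR adjusted p = 0.00086) and Adam10, a membrane protease (9:70551094-70570578; 161 and 450 reads, edgeR adjusted p = 0.0013), none of them listed in the untreated libraries. The falls of smallest p were an intronic circRNA of Epha5 (5:84552984-84553162; 32 and 94 reads untreated and not listed in treated, edgeR adjusted p = 7.2e-05), 1 listed as intergenic that spans Hamp and Usf2 (7:31711855-31731688; 39 and 38 reads untreated and not listed in treated, edgeR adjusted p = 0.00014), and 1 listed as intergenic across 7 loci of the H2 region from H2-D1 to H2-Q8 (17:35400784-35562322; 8 and 5 reads treated, 87 and 63 untreated, log2 change -6.44, edgeR adjusted p = 0.00016). The H2 genes are near-identical copies, so the ends of that junction are uncertain.

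Of 9976 circRNAs in at least 2 libraries edgeR called 185, 53 higher and 132 lower after RNase R, with 2446 at an unadjusted p under 0.05. With the SSC number as a block it called 82 higher and 51 lower. The median fitted log2 change of all tested circRNAs was 4.64, the opposite of the called majority, and it depends on the prior count, since 6207 of them were not listed in the untreated libraries. Among intergenic circRNAs 57 of 694 fell (8.21%), against 66 of 8115 exonic (0.81%) and 9 of 1167 intronic ones (0.77%), and this difference was not tested. All 91 tested circRNAs that the treated libraries did not list were called lower, and 38 of the 6207 that the untreated ones did not list were called higher. A circRNA absent from the treated libraries is tested only when both untreated libraries list it, so the number of falls depends on this minimum and on the entries of 0. Without TMM the test called 37 higher and 292 lower, DESeq2 18 and 151, and the tests of circRNAs in any library 171 and 385. With RNase R replicate 1 left out the count was 73, and without replicate 2 it was 69. The calls for the circRNAs over Elf2, between Rbmxl2 and Syt9 and of Cnot6l ended with DESeq2 (adjusted p = 0.211, 0.131 and 0.244), without TMM (edgeR adjusted p = 0.359, 0.341 and 0.396), with circRNAs listed in any library (edgeR adjusted p = 0.774 for each) and without any 1 of the 4 libraries, with edgeR adjusted p = 0.579, 0.397 and 0.482 without RNase R replicate 1 and 0.917, 0.793 and 0.917 without replicate 2. Their log2 changes depended on the scaling, with 0.79, 0.85 and 0.72 in DESeq2 and 0.45, 0.53 and 0.41 without TMM.

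Host genes with the most circRNAs in at least 2 libraries were Glis3, a zinc finger transcription factor (26, at 19:28336938-28754567), Ptk2, the focal adhesion kinase (26, at 15:73035535-73253621), Atp9b (23, at 18:80930880-81130797), Mllt10 (23, at 2:17976898-18134017) and Arhgap10 (22, at 8:79774265-80041806). Of 3556 host genes 48.0% had 1 such circRNA and 14.7% had 5 or more. The SSCs have no FPKM values, so host levels were read in priSG-A, the nearest stage. The priSG-A libraries also held transcripts of Sertoli cell genes (Clu at 774.5 and 830.8, Amh at 81.67 and 61.07), so these levels may include RNA of another cell type. The 761 expressed hosts of circRNAs found in all 4 libraries had a median log2(FPKM + 1) of 3.97 there, against 3.02 for the other 13350 expressed genes (difference 0.95, two-sided permutation p = 1e-05, the smallest that 100000 resamples can give; genes are not independent replicates). Among genes at 5 FPKM or more in at least 2 libraries the difference was 0.44. Host loci were longer, with a median of 85718 bases against 18711.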

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

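The edgeR test on effective fragments, the weights per stage and the length-matched resampling were chosen only after the results were seen. Named genes, circRNAs and lists were repeated 6141 times under the alternatives. Settings such as eBayes without trend or a weight per stage leave the log2 change of a gene as it was, so they could not turn it. Of the repeats, 5455 either kept a call with its direction or were called in neither setting, where directions were not compared. A further 659 lost the call, 25 gained it and 2 changed direction, which for a list is the direction of camera. Both of the last were lists from plpSC to pacSC without pacSC replicate 2, round spermatid (median -1.196, range -1.196 to 0.648 with each library left out) and Leydig cell (median -0.969, range -0.969 to 2.141). With an estimated correlation camera called 0 lists at each step, against 15, 14 and 11 with the preset one, with 0, 1 and 1 lists at an unadjusted p under 0.05. The X-linked difference was then not called at the steps to pacSC (-0.919, camera adjusted p = 0.0903) and to rST (0.384, camera adjusted p = 0.17). The cause of these changes was not tested.

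From plpSC to pacSC, 3646 called genes became 2326 after quantile normalization, 680 with only the 4 libraries compared, 1 with weights per stage and 2235 with a 2-fold minimum, the last by construction. Leaving out 1 library gave 1074 to 7263 genes at this step, 6468 to 10748 at the step to plpSC and 2 to 7364 at the step to rST, 10945 to 13234 over the 4 stages, and 14 to 15, 9 to 15 and 10 to 12 lists at the steps to plpSC, pacSC and rST. List medians near 0 changed sign with scaling, as given beside each list, and without plpSC replicate 2 the medians of the pachytene and retrogene lists at the step to pacSC changed sign (0.397 to -0.092 and 0.43 to -0.226). With 1 library left out the X-linked difference ranged from -0.598 to -0.217, from -1.034 to -0.789 and from 0.348 to 0.429 at the same steps, and with a pseudocount of 0.1 it was -0.544, -1.491 and 0.758. The calls between quantile normalization and the values as deposited shared 1648 genes. As deposited, the medians of the round spermatid, retrogene and endothelial lists at the step to pacSC were -0.094, 0.43 and -0.649. Quantile normalization ended their calls (medians -0.041, 0.41 and -0.115, camera adjusted p = 0.772, 0.0519 and 0.44). At the step to rST quantile normalization ended the call of the transcription regulators (median 0.112 against 0.297 as deposited, camera adjusted p = 0.0854). The cause was not tested.

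With the replicate number as a block, 8967, 2944 and 4370 genes were called at the 3 steps, 12341 over the 4 stages, and 15, 14 and 11 lists. Across genes, deviations of the replicates correlated at 0.38 between priSG-A and plpSC, -0.137 between plpSC and pacSC and 0.152 between pacSC and rST, and at -0.314 to -0.151 between the other stages, with no common sign, and the labels name no pairs. With the SSC number as a block edgeR called 133 circRNAs (82 higher and 51 lower), against 185 (53 and 132) without it, and 77 were shared. Deviations between SSC replicates correlated at 0.199 between the treated and the untreated libraries over 1195 circRNAs. The labels do not say whether a number stands for a shared culture. Without TMM 329 circRNAs were called, with any library as the minimum 556, and 69 to 175 with 1 library left out. When thinned, treated libraries listed a mean of 2953 circRNAs and untreated ones 2781.5. With at least 5 junction reads the means were 11758.5 and 1357.5. Those in all 4 libraries were 628 at 5 reads and 286 at 10 reads. The exon share was 79.6% (treated) and 79.2% (untreated) at 5 reads, against 76.4% and 76.8%. The causes were not tested beyond the smaller number of circRNAs that each minimum leaves. The host gene difference kept its sign and its call in the 3 alternatives run, with a smaller size at 5 FPKM (1.262 with hosts in any library, 0.436 at 5 FPKM, and an excess of 1.017 over length-matched resamples). The alternatives for the circular share at the junction were not run, since the lists lack non-junction reads.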

Other observations

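The tests of sources of RNA, of a mislabelled library and of junction read numbers were chosen only after the results were seen. The ribosomal protein list and the list of circular RNA biogenesis factors were called down from priSG-A to plpSC, calls that ended with an estimated correlation (adjusted p = 0.556 and 0.578). The long non-coding RNA list was not called by camera at any of the 3 steps. Of 32 ribosomal protein genes 25 fell from priSG-A to plpSC (28 adjusted over the list alone; median -1.22, camera adjusted p = 0.000108, and adjusted p = 0.556 with an estimated correlation), 3 fell in pacSC (3 adjusted over the list alone; median -0.44, camera adjusted p = 0.123, and adjusted p = 0.855 with an estimated correlation) and 4 in rST (2 adjusted over the list alone). The rST median was -0.13 (camera adjusted p = 0.145, and adjusted p = 0.931 with an estimated correlation). Rpl14 went from 570.2 ± 6.19 in priSG-A to 169 ± 49.3, 107 ± 24 and 39.9 ± 9.82 in plpSC, pacSC and rST. The ribosomal list was called downward at the step to pacSC without pacSC replicate 1 (camera adjusted p = 0.000886) and at the step to rST without pacSC replicate 2 (0.00438). After quantile normalization it was called at both (camera adjusted p = 3.91e-05 and 0.000416).

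Of 25 circular RNA biogenesis factors 15 fell and 1 rose from priSG-A to plpSC (16 and 1 adjusted over the list alone; median -0.85, camera adjusted p = 0.0423, and adjusted p = 0.578 with an estimated correlation), a call that ended without plpSC replicate 1 (camera adjusted p = 0.0974) or priSG-A replicate 1 (0.062). In pacSC 6 fell and 1 rose (6 and 1 adjusted over the list alone; median -0.07, 0.33 after centring, mean -0.32, camera upward, adjusted p = 0.727, and adjusted p = 0.944 with an estimated correlation). In rST 14 fell and 2 rose (14 and 2 adjusted over the list alone; median -0.77, camera adjusted p = 0.00118, and adjusted p = 0.733 with an estimated correlation), with Hnrnpl, a splicing regulator, going from 87.4 ± 9.66 to 18.4 ± 4.53 and the neuronal and germ cell splicing factor Ptbp2 from 77.2 ± 10.3 to 22.7 ± 2.77. Of 25 long non-coding RNAs 14 fell and 4 rose from priSG-A to plpSC (14 and 4 adjusted over the list alone). The median was -0.78 (camera adjusted p = 0.268, and adjusted p = 0.684 with an estimated correlation). In pacSC 5 fell and 3 rose (9 and 4 adjusted over the list alone; median -0.46, mean -0.38, camera upward, adjusted p = 0.935, and adjusted p = 0.973 with an estimated correlation). In rST 7 fell and 3 rose (8 and 3 adjusted over the list alone). The median was -0.54 (camera adjusted p = 0.115, and adjusted p = 0.784 with an estimated correlation). Snhg3, a host of small nucleolar RNAs, rose from 45.5 ± 7.66 in plpSC to 152 ± 10.1 in pacSC and fell to 42.9 ± 0.0642 in rST, and Terc, the telomerase RNA, fell from 74.1 ± 7.93 in priSG-A to 15.5 ± 10 in plpSC.

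In pacSC replicate 2, spermatid and Leydig transcripts stood above replicate 1 (Prm1 2340 against 66.1, Insl3 492 against 17.3, Cyp17a1 152 against 7.12). Over 47 spermatid genes the excess was a median 14.9% of the rST level (quartiles 12.7 to 16.9), and 95.7% of them lay within 2-fold of it, so round spermatid RNA is a candidate source. The rST libraries as the only source are excluded by the Leydig genes, whose median ratio of pacSC replicate 2 to rST was 7.42 over the 12 expressed members of a list of 15, none of them on another list. Leydig RNA may thus be a second source. The pacSC cells were taken at 17 days and the rST cells at 60 days. Whether the 17-day testes held round spermatids is not known from these data. The step at which spermatid or Leydig RNA would have entered therefore stays open. Both libraries carry the same stage label, so no biological explanation was tested.

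Both plpSC libraries held pachytene transcripts at a high level (Ldhc 1943 and 803, Hspa2 913 and 404, against 977 and 889 for Hspa2 in pacSC). Both genes were also high in rST (Ldhc 1985 and 1917, Hspa2 760 and 742). The 265 genes compared were chosen by their pacSC and priSG-A levels, so they do not tell pachytene RNA from that of later cells. In replicate 2, 87.2% of them lay within 2-fold of a median share of 43.8% of the pacSC replicate 1 level (quartiles 37.1 to 52.2). Shares of single genes differed, with Piwil1 at 25.1 against 103.5 and Pgk2 at 111.4 against 134.8. Pachytene RNA mixed in is thus 1 candidate source, and sedimentation by size would be the step to remove it. Of the 30 genes of the pachytene list, 13 are also on another list. In replicate 1, 83.4% of the 265 genes lay within 2-fold of a median share of 109.7% (85.7 to 136.6), which leaves mixing open. There Acrv1 (139 against 31.1) and Pgk2 (279 against 134.8) lay above pacSC replicate 1, and Piwil1 (29.7 against 103.5) below. The protamine and transition protein genes made up 0.06% and 0.05% of the FPKM sum in plpSC, against 6.59% and 7.4% in rST. Acrv1 (139 and 41.2 in plpSC, 237 and 261 in rST) and Actl7b (358 ± 258 and 656 ± 33.8) were far closer. For these genes the values argue against RNA like that of the rST libraries as the main source in plpSC. Spermatid RNA of another make-up was not tested. The X-linked minus autosomal level of replicate 1 was -0.638 against -1.59 and -1.58 in pacSC. This argues against a pachytene library like those of pacSC under its label. A pachytene library mixed with other cells is not excluded, since RNA of cells without silenced sex chromosomes would raise this level. Replicate 1 also held transcripts that were low in pacSC (Dcn 44.1 against 2.17 and 3.45, Hba-a1 189 against 0.779 and 0.168). Transcription of the pachytene genes in plpSC cells themselves stays open. The meiotic list had 0.96 times the plpSC to pacSC ratio of the pachytene list in replicate 1 and 2.94 times in replicate 2.

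RNase R libraries listed more circRNAs than untreated ones. At equal junction reads the treated libraries listed 1.06 times as many, which is consistent with the number of junction reads as the source of the difference. The test does not say why the treated libraries held more junction reads, and enrichment of circular over linear RNA stays open.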
